A study of Homo sapiens with 4 samples.

How the data were processed

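Gene expression was measured with a 1-colour Illumina bead array in 4 RNA samples. Each of 4 groups held 1 array, and every group was taken from the labels. MDA-MB-231 is a breast cancer line, and MCF10A is a non-tumorigenic breast epithelial line. The labels name MDA-MB-231 cells, untreated MCF10A cells, MCF10A cells given MDA-MB-231 exosomes, and MCF10A cells given MDA-MB-231 exosomes with a Dicer antibody inside. Total RNA was turned into biotin-labelled RNA copies by reverse transcription and in vitro transcription. Mature microRNAs were not measured by this assay. The extraction notes cover RNA from exosomes as well as from cells, and the sample labels name only cells, so whether any array held exosome RNA was not settled by the labels.

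The deposited non-normalized table gives 1 intensity per probe and array, on a linear scale, without background subtraction. Beside each intensity stands a deposited detection p-value, the probe's rank against the negative control probes of the same array. The number of those controls and the scanner software were not given in the sources used here. The authors also deposited a value table, whose columns for the MDA-MB-231, untreated and Dicer antibody arrays hold intensity values normalized between arrays, with medians of 55.1, 55.3 and 55.3. Its column for the exosome array holds the detection p-value in place of a signal, with a median of 0.423, and lay within 0.0026 of the detection p in the non-normalized table at every probe. The value table is neither logged nor centred, and the normalization behind it was not stated. On the other 3 arrays it keeps the order of the scanner signals (Spearman's rho at least 0.99998). limma was used by the authors, per the submitters' processing notes, in a version that was not given in the sources used here.

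The 47322 probes were named from the platform annotation, with symbols matched to current ones by gene identifier for 30071 probes. A single gene symbol was available for 30110 probes, several for 8 and none for 17204. Only probes with a single symbol entered the comparisons of genes. Genes on the Y chromosome and XIST were left out.

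Signals were background-corrected, quantile-normalized over the 4 arrays and logged with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16. Control probes were not used here, so neqc estimated the background from the detection p-values. A probe was called detected at a detection p below 0.01. Each gene was represented by its probe with the highest mean normalized value over the 4 arrays, which gave 19948 genes on the array, of which 12445 were detected on at least 1 array. A comparison used the genes detected on at least 1 of its 2 arrays. For a gene detected on only 1 of them, the difference is a bound, taken against the higher of the lowest detected value on the dimmer array and the gene's own value there, and set to 0 where that bound left no difference. Such bounds are written with "at least", at the smallest size over 6 scalings of the arrays. Signals are given as deposited, background included. Folds without "at least" come from background-corrected, quantile-normalized values, unless the text says otherwise. Both steps change ratios, so these folds can exceed the ratio of the signals printed beside them. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

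With 1 array per group there was no replicate spread, so no p-value, standard error or confidence interval could be given for any difference between groups, and the number of arrays limits the precision. Genes with a difference of at least 2-fold (1 on the log2 scale) were counted. Each of 25 gene lists was summarised by its median log2 difference and by its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list of at least 3 measured genes was called outside the range of random lists when its median lay beyond their central 95%. These percentiles describe these arrays only. Where most differences are bounds set to 0, the medians of random lists collapse to 0 and any other median falls outside their range. This was so in the 3 comparisons that join an array with few detected probes to one with many. There the central range ran from 0 to 0 for 17 to 19 of 24 lists, and percentiles were given no weight. The lists described there include every list outside the range. After quantile normalization the lowest detected log2 value was 9.64 on the MDA-MB-231 array and 9.66 on the exosome array. On the untreated and Dicer antibody arrays it was 4.83 and 4.82. A gene not detected on an array with few detected probes could thus count as lower there only if it was bright on the other array. The lists hold 567 genes, 529 with a probe. They cover epithelial junction and keratin genes, mesenchymal genes, epidermal differentiation, the microRNA machinery, targets of miR-21, miR-10b and miR-155, exosome formation, cell cycle, interferon response, NF-kB inflammatory genes, the ATF4 stress response, hypoxia and glycolysis, p53 targets, sterol synthesis, growth factor and immediate early genes, the TGF-beta and matrix response, metallothioneins, heat shock, ribosomal proteins, oxidative phosphorylation, and markers of luminal breast cells, fibroblasts, leukocytes and endothelium.

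The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. Genes were named when they were among the 10 largest measured differences each way, the 4 largest bounds each way, or the 4 largest differences of at least 2-fold in a list, and DICER1, AGO2, TARBP2, HOXD10, CDH1 and VIM were always looked up. Names were left out for length. In the comparisons that join an array with few detected probes to another array, the genes named with a direction were further limited, after their values were seen, to those at least 2-fold different the same way under all 6 scalings tried, unless the text says otherwise. A further 4 choices were made after the data were seen: using the log2 of the deposited signals alone, skipping the normalization between arrays, normalizing the arrays with many and with few detected probes apart, and comparing the exosome array with the MDA-MB-231 array. The other alternatives were quantile normalization with no background correction, median scaling, the authors' value table, an offset of 50, a detection p below 0.05, only genes detected on both arrays, no detection filter, and the mean over a gene's detected probes.

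Detection set the depth of each array. Of 47322 probes, 2573 (5.44%) were detected on the MDA-MB-231 array, 2526 (5.34%) on the exosome array, 19150 (40.5%) on the untreated array and 19261 (40.7%) on the Dicer antibody array. Median signals were 51.8, 52.7, 58.7 and 62.5 units in the same order.

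The steps were tested on simulated data, made by copying an array, adding noise with a log2 SD of 0.1 and changing 200 genes by 2-, 4- or 8-fold. Copies of the untreated array returned 100.0% of 4-fold and 8-fold changes as at least 2-fold different, and 17.9% to 26.9% of 2-fold changes, whose median estimate was 0.91 to 0.92 on the log2 scale. None of the unchanged genes was called in those 3 simulated comparisons. Copies of the arrays with few detected probes returned less. From the exosome array, 28.4% of 4-fold and 100.0% of 8-fold changes were called, with 1 false call, and from the MDA-MB-231 array, 0 of 67 genes changed 4-fold and 68.2% of those changed 8-fold, with a median estimate of 1.10 for the latter. When all signal above background on 1 copy was dimmed to 5.0% of its level, quantile normalization called 3.65% of unchanged genes, and leaving the arrays unnormalized called 84.0% of them lower. The loss on the arrays with few detected probes was not even, as described below, so these rates do not carry over to them. For MDA-MB-231 against untreated, quantile normalization set the median log2 difference of genes detected on both arrays at 3.28.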

Results

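Transcript levels were measured on 4 arrays, 1 per group, to ask how vesicles from breast cancer cells alter non-tumorigenic breast cells and whether the microRNA-processing enzyme Dicer inside those vesicles matters. The groups, named here as labelled, are MDA-MB-231 cells, MCF10A cells left untreated (the untreated array), MCF10A cells given MDA-MB-231 exosomes (the exosome array), and MCF10A cells given exosomes that carried a Dicer antibody (the Dicer antibody array). Every difference is between 2 single arrays, without replicates and so without a test, and every group name is that of the label.

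The arrays fell into pairs by how much they detected. The untreated and Dicer antibody arrays detected 11107 and 11081 genes, and the MDA-MB-231 and exosome arrays detected 1584 and 1566. Genes present at high levels in nearly all cells followed this split. All 38 measured ribosomal protein genes and all 28 genes of oxidative phosphorylation were detected on the untreated array and on the Dicer antibody array. Of 66 such genes, 21 were detected on the MDA-MB-231 array and 22 on the exosome array. Lactate dehydrogenase A (LDHA), a glycolytic enzyme, read 17537 and 11949 units on the untreated and Dicer antibody arrays and 63.3 and 53.9 units on the MDA-MB-231 and exosome arrays, where it was not detected. The 100 brightest probes held 61.8% and 51.0% of the signal above the median on the MDA-MB-231 and exosome arrays, against 9.56% and 11% on the untreated and Dicer antibody arrays. A comparison across the pairs therefore sets an array with few detected probes against one with many, and the groups cannot be told apart from this split there. Folds for single genes in such comparisons, and in the comparison of the exosome and MDA-MB-231 arrays, are therefore the smallest over 6 scalings of the arrays, 1 of them the deposited signals alone. Printed signals are as deposited, while other folds follow background correction and quantile normalization and can exceed the ratio of the signals.

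**Figure D1:**
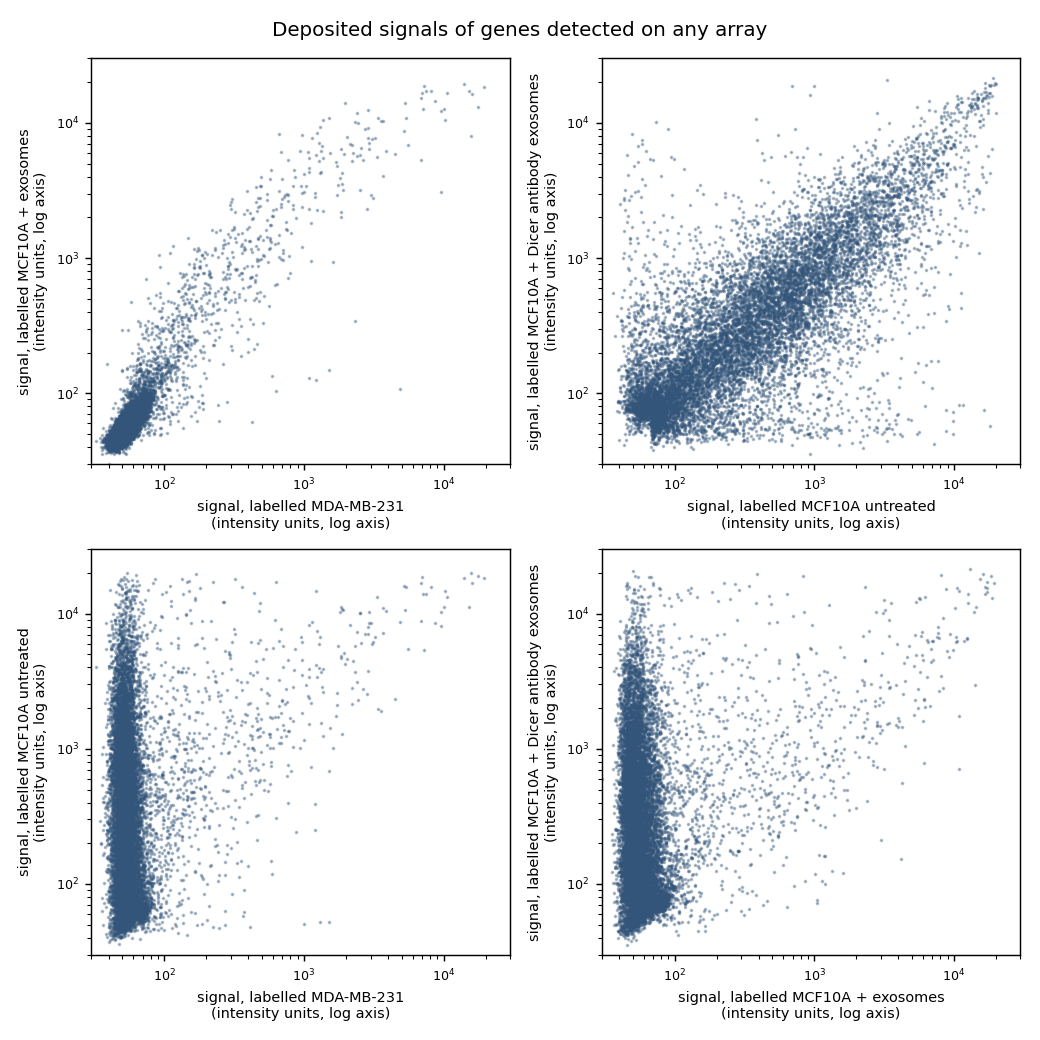
Each point is a gene detected on at least 1 of the 4 arrays, placed by its deposited signal on 2 arrays (intensity units, log axes). The MDA-MB-231 and exosome arrays follow each other, as do the untreated and Dicer antibody arrays, while most genes bright on the latter pair lie at background on the former.

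Cell type markers did not match the label of the untreated array, nor clearly that of the Dicer antibody array, which also names MCF10A. MCF10A is an epithelial line, yet the keratins of basal epithelium KRT5 and KRT14 and E-cadherin (CDH1), the main adhesion protein of epithelia, were not detected on any of the 4 arrays. On the untreated array 8 of 33 epithelial genes were detected, whereas all 10 fibroblast markers were, with a median signal of 6362 units. These included the collagen gene COL1A2 at 18125 units and lumican (LUM), a matrix proteoglycan, at 8848 units. The Dicer antibody array detected 15 of the 33 epithelial genes and 5 of the 10 fibroblast markers, the latter at a median of 85.8 units. Over all 19948 genes the Dicer antibody array detected 11081, a higher share than of the epithelial genes. Median signals of the epithelial list were low on both, at 54.2 units on the untreated array and 66.3 on the Dicer antibody array. These lay at percentiles 0.465 and 12.6 of random lists on the same array. The mesenchymal list lay at percentile 99.9 on the Dicer antibody array. No fibroblast marker was detected on the MDA-MB-231 array or on the exosome array, where few genes of any kind were detected. Luminal breast markers were detected for 2 of 10 genes on the untreated array and 3 of 10 on the Dicer antibody array. All 28 mesenchymal genes were detected on the untreated array, 26 on the Dicer antibody array and 3 on each of the other arrays. Directions given against the untreated array are for the RNA on the array with that label.

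**Figure D2:**
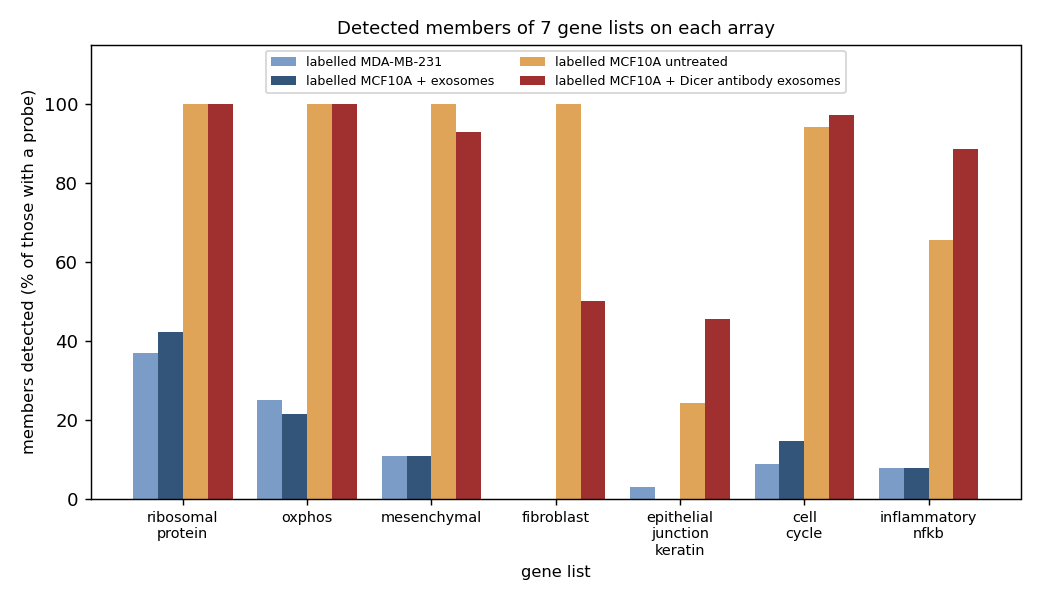
Bars give the percentage of measured members of 7 gene lists that were detected on each array. Fibroblast and mesenchymal genes were detected throughout on the untreated array. The MDA-MB-231 and exosome arrays detected fewer members of each list than the untreated and Dicer antibody arrays, with the most for ribosomal protein genes, 14 and 16 of 38.

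The Dicer antibody array against the untreated array is the only planned comparison within the pair with many detected probes. By its labels it asks what exosomes do when their Dicer is blocked, though KRT5, KRT14 and CDH1 were not detected on either array. The collagen-degrading protease cathepsin K (CTSK) read 16558 units on the untreated array and 74.5 on the Dicer antibody array, 406-fold lower, and COL1A2 was at least 242-fold lower, at 18125 against 57.6 units. The smooth muscle protein transgelin (TAGLN) was 191-fold lower and the chemokine CXCL12 171-fold lower. In the other direction, L-plastin (LCP1), an actin-bundling protein of blood and tumour cells, read 10094 against 74.0 units, 184-fold higher, and the tryptophan-degrading enzyme TDO2 was 134-fold higher. The homeobox factor IRX2 was 49.7-fold higher, at 18811 against 689.7 units, and 28.6-fold higher with no normalization between arrays. Without background correction the folds of CTSK, TAGLN, CXCL12, LCP1 and TDO2 were 173, 57.9, 47.9, 50.4 and 39.8. Of 88 named genes measured on both arrays and at least 2-fold different, 59 had a fold smaller by more than 1.5 times under that setting.

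Of 12247 genes compared, 3865 differed by at least 2-fold, 1815 higher and 2050 lower on the Dicer antibody array. Of these, 340 higher and 437 lower genes were detected on only 1 of the arrays, so that their differences are bounds. All 10 fibroblast markers were compared and 9 were lower, with a median log2 difference of -4.93. LUM was at least 35.9-fold lower, the surface glycoprotein THY1 at least 25.1-fold lower, and the growth factor receptor PDGFRB 39.7-fold lower. Of 28 mesenchymal genes, 19 were lower and 2 higher, with a median of -2.07. Among them the collagen cross-linking enzyme LOX was 32.2-fold lower, smooth muscle actin (ACTA2) 24.5-fold lower and COL6A1 20.8-fold lower, while vimentin (VIM) differed by only -0.46 on the log2 scale. In the TGF-beta and matrix list, 12 of 25 genes were lower and 2 higher (median -0.82). LTBP2, a protein of matrix microfibrils, was 34.5-fold lower and the matrix protease MMP3 19.6-fold lower, whereas the morphogen BMP2 was at least 4.06-fold higher.

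Inflammatory genes driven by NF-kB stood at the opposite end. Of 23 measured genes of this list, 21 were higher, with a median log2 difference of 2.93. The neutrophil-attracting chemokine CXCL2 was 79.2-fold higher, interleukin-1 beta (IL1B) 49.6-fold higher and IL1A at least 8.55-fold higher, and the only lower member was the monocyte-attracting CCL2, by 90.2-fold. Cell cycle genes were higher for 28 of 33 members and lower for none (median 2.0). They included CDC20, an activator of the anaphase-promoting complex, 15.2-fold higher, the ribonucleotide reductase subunit RRM2, 14.8-fold higher, UBE2C, 9.29-fold higher, and the mitotic kinase AURKB, 8.72-fold higher. In the ATF4 stress list 11 of 22 genes were higher and 1 lower, with TRIB3 17.9-fold and asparagine synthetase (ASNS) 11.5-fold higher. Growth factor and immediate early genes were higher in 10 of 22 cases and lower in none, led by MYC, a transcription factor that drives growth, at 15.6-fold.

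Epithelial genes were higher for 7 of 16 members and lower for 1 (median 0.68). The laminin chain LAMB3 was 27.1-fold higher, keratin 7 (KRT7) 10.05-fold higher and claudin 1 (CLDN1) at least 4.80-fold higher. Epidermal differentiation genes were higher for 7 of 13 and lower for none (median 1.04), with the protease inhibitor PI3 at least 4.46-fold higher. Among 4 luminal markers 2 were higher. Of 20 p53 targets, 10 were lower and 2 higher (median -1.0). TP53I3 was 9.92-fold and PHLDA3 9.80-fold lower, but GDF15, a stress cytokine also made through other routes, was 34.8-fold higher. Sterol synthesis genes were lower for 9 of 17 and higher for none (median -1.02), with lanosterol synthase (LSS) 5.13-fold and INSIG1 5.12-fold lower.

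DICER1 itself read 326.6 units on the untreated array and 280.5 on the Dicer antibody array, a log2 difference of -0.07 after normalization. Of 20 genes of the microRNA machinery, 4 were higher and 1 lower (median 0.20). Exportin 5 (XPO5), which carries microRNA precursors out of the nucleus, was 3.97-fold higher and the Argonaute AGO2 2.43-fold higher, while the Dicer partner TARBP2 differed by -0.77 on the log2 scale. Targets of miR-10b were lower for 4 of 9 genes and higher for none (median -0.81, outside the range of random lists), among them the cell cycle inhibitor CDKN1A, 5.45-fold lower. Its target HOXD10 was not detected on either array. Targets of miR-21 split into 4 higher and 4 lower of 15 (median 0.14), with the matrix protease inhibitor RECK at least 10.7-fold lower and RHOB 8.96-fold higher. Targets of miR-155 were higher for 3 and lower for 2 of 16 (median -0.10).

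The other lists moved little or in mixed directions. Ribosomal protein genes were within 2-fold for 33 of 38 members, with a median of 0.35 that still lay above 99.5% of random lists. Of 28 oxidative phosphorylation genes 26 were within 2-fold (median 0.16). Interferon response genes split into 10 higher and 6 lower of 30 (median 0.03), from OASL 13.2-fold higher to TRIM22 18.5-fold lower. Hypoxia and glycolysis genes were higher for 4 and lower for 3 of 22 (median 0.30), with the angiogenic factor VEGFA 14.4-fold higher. Heat shock genes were lower for 4 and higher for 1 of 13 (median -0.33), the small heat shock protein CRYAB by 144-fold. Of 7 metallothioneins 2 were higher and 2 lower (median 0.05). Exosome formation genes were within 2-fold for 16 of 20 (median -0.26). Leukocyte markers gave 1 higher and 1 lower of 6 (median 0.05) and endothelial markers 1 higher and 1 lower of 3 (median -0.58).

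**Figure D3:**
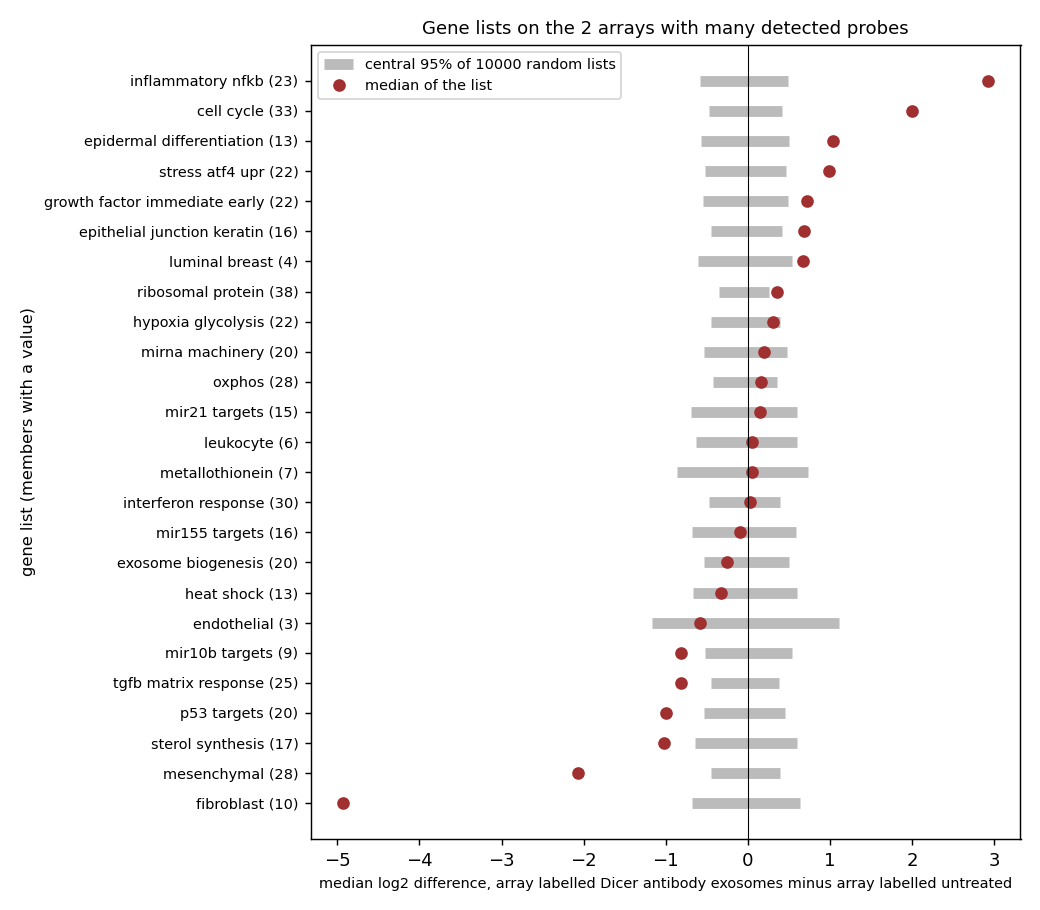
Points give the median log2 difference of each gene list, Dicer antibody array minus untreated array, and grey bars the central 95% of 10000 random lists matched on size and expression. The inflammatory list (2.93) and the cell cycle list (2.0) lay farthest above, and the fibroblast list (-4.93) farthest below.

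In all, 14 of the 25 lists lay outside the range of random lists, and each of these 14 kept the sign of its median under every alternative tried. The sizes held less well. Of the 14 medians, 7 were smaller by more than 1.5 times without background correction, 7 with an offset of 50, 4 with no detection filter, 3 in the authors' value table and 2 under median scaling. The largest losses came with no detection filter, where the luminal median became 0.035, epidermal differentiation 0.071 and epithelial genes 0.13, and under median scaling, where the ribosomal median became 0.050. Without background correction and with an offset of 50, in that order, the inflammatory median became 1.72 and 1.75, cell cycle 1.09 and 1.08, p53 targets -0.48 and -0.47, miR-10b targets -0.37 and -0.36, and epithelial genes 0.32 and 0.30, while the TGF-beta and matrix median was larger in size, at -1.30 and -1.27. Larger by more than 1.5 times were also the luminal median over genes detected on both arrays and the ribosomal median as a mean over probes. Where a gene had 2 detected probes, its second probe differed the same way in 93.5% of 844 genes called 2-fold by the first. Fewer genes differed by 2-fold with an offset of 50 (1571), with no background correction (1616) and in the authors' value table (2527). The share of the called genes that was higher was 47.0%, and 36.4% under median scaling, which set the median of genes detected on both arrays at -0.23.

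MDA-MB-231 against the untreated array asks how the cancer line differs from the line that received its exosomes, and it crosses the split in detection. COL1A2 was at least 19.2-fold lower on the MDA-MB-231 array, the metastasis-associated calcium binding protein S100A4 at least 19.3-fold lower, and the matrix protein tenascin C (TNC) at least 13.8-fold lower. Beta-actin (ACTB) read 149.5 against 17538 units and was at least 5.12-fold lower, and the ribosomal protein gene RPS19 read 55.2 against 17393 units and was at least 16.8-fold lower. FOSB, an immediate early transcription factor, read 588 against 118 units and was at least 4.98-fold higher, and the platelet-derived growth factor gene PDGFA, at 1312 against 52.7 units, was at least 19.3-fold higher. The hydroxysteroid dehydrogenase gene HSD17B8 and the deubiquitinase OTUB1 were at least 3.06-fold and 4.13-fold higher.

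By list, fibroblast markers were lower for 7 of 10 genes and mesenchymal genes for 13 of 28, with none higher in either. TGF-beta and matrix genes were lower for 11 and higher for 1 of 22, among them TGFBI and thrombospondin 1 (THBS1), at least 13.5-fold and 8.22-fold lower. Ribosomal protein genes were lower for 20 and higher for 4 of 38, and oxidative phosphorylation genes lower for 14 and higher for none of 28, with COX4I1 at least 6.05-fold lower. The medians of these 5 lists ran from -0.72 for mesenchymal genes to -1.90 for fibroblast markers, and under median scaling from -6.18 to -7.39 for the same lists. Random lists were no yardstick here, because most bounds were 0 and so were the medians of random lists. These 5 are the lists whose medians lay outside random lists, so their choice carries no weight. Among the lists left out, hypoxia and glycolysis genes were lower for 7 and higher for 2 of 21. Over genes detected on both arrays alone, the medians of the ribosomal and oxidative phosphorylation lists were 0.45 and 0.090, from 14 and 7 genes, and the TGF-beta list held 1 gene, at 4.69. DICER1 and AGO2 were not detected on the MDA-MB-231 array, at 53 and 54.5 units, and no fold could be given. RAN, a nuclear transport GTPase of the microRNA list, was 2.15-fold higher and the heat shock co-chaperone DNAJA1 4.32-fold higher after quantile normalization, and both were lower under median scaling.

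In total 2026 of 11354 genes differed by at least 2-fold, 1399 higher and 627 lower. The balance rested on the scaling, since with no normalization between arrays 9617 differed, 48 higher and 9569 lower, and median scaling gave 76 higher and 8989 lower. Under all 6 scalings 33 genes stayed at least 2-fold higher and 475 at least 2-fold lower.

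The exosome array against the untreated array addresses the effect of cancer exosomes on MCF10A cells, and it crosses the same split. It resembled the previous comparison. The genes lower on the exosome array again included COL1A2, at least 18.9-fold, S100A4, at least 19.0-fold, and TNC, at least 13.6-fold. The cell cycle inhibitor CDKN1A read 93.0 against 15095 units and was at least 8.07-fold lower, ACTB at least 9.15-fold lower and VIM at least 7.65-fold lower. Genes higher on the exosome array included the histone methyltransferase EZH2, at 1278 against 117 units and at least 8.77-fold, the small GTPase RAC3, at least 11.1-fold, the carnosine methyltransferase CARNMT1, at least 17.8-fold, and PDGFA, at least 63.1-fold. The mitotic kinase PLK1 was at least 2.36-fold higher.

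Lists were again read by their members alone. The first 5 named are those whose medians lay outside random lists, a choice that carries no weight. Among the lists left out, hypoxia and glycolysis genes were lower for 6 and higher for 3 of 22. Fibroblast markers were lower for 7 of 10 genes and mesenchymal genes for 13 of 28, with none higher, and TGF-beta and matrix genes were lower for 11 and higher for 1 of 22. Ribosomal protein genes were lower for 20 and higher for 5 of 38, among them RPL19, at least 12.6-fold lower. Oxidative phosphorylation genes were lower for 14 and higher for 2 of 28, with the ATP synthase subunit ATP5F1B at least 8.80-fold lower. The cell cycle list gave 5 higher and none lower of 32, and its median was 0. The absence of lower members carries no weight, because none could have been called lower. Its brightest member read 1197.6 units on the untreated array. PHLDA1, at 3628 units there and not detected on the exosome array, reached a log2 bound of only -1.05. Over genes detected on both arrays alone, the medians of the ribosomal and oxidative phosphorylation lists were 0.24 and 0.50, from 16 and 6 genes, and the TGF-beta list held 1 gene, at 4.41. Under median scaling the fibroblast and mesenchymal medians were -7.08 and -5.86. RAN was 3.06-fold higher after quantile normalization and lower when pairs of arrays were normalized apart. DICER1 and TARBP2 were not detected on the exosome array, at 47.7 and 72.2 units.

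In total 1969 of 11322 genes differed by at least 2-fold, 1361 higher and 608 lower. With no normalization between arrays 8814 differed, 165 higher and 8649 lower, and median scaling gave 207 higher and 8289 lower. Under all 6 scalings 95 genes stayed higher and 463 stayed lower.

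The Dicer antibody array against the exosome array asks what blocking Dicer in the vesicles changes, and it too crosses the split. The chemokine CXCL8 read 20768 against 50.7 units and interleukin-6 (IL6) 18620 against 54.9, at least 24.0-fold and 18.9-fold higher on the Dicer antibody array, and GDF15 was at least 7.57-fold higher. IRX2 was at least 19.6-fold higher. Lower genes included CRYAB, a small heat shock protein, at 75.7 against 1047 units and at least 13.8-fold, the lectin SIGLEC12, at least 20.1-fold, the invadopodium protein SH3PXD2A, at least 10.8-fold, and the transcription factor BCL11A, at least 6.13-fold.

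Ribosomal protein genes were higher for 24 and lower for 3 of 38 (median 2.31), with RPS25 at least 16.4-fold higher. Oxidative phosphorylation genes were higher for 14 and lower for 2 of 28 (median 1.02). The ATF4 stress list gave 8 higher and 1 lower of 22, including ATF4 itself at least 6.45-fold higher. Hypoxia and glycolysis genes gave 5 higher and 4 lower of 22, with enolase (ENO1) at least 16.1-fold higher, and metallothioneins 2 higher and none lower of 6, with MT2A at least 8.47-fold higher. The medians of the ATF4 stress and hypoxia lists were 0.08 and 0.03, and 4.86 and 4.84 under median scaling. Over genes detected on both arrays alone, the medians of the ribosomal, oxidative phosphorylation, stress and hypoxia lists were -0.094, -0.137, -0.746 and -1.349, from 16, 6, 3 and 6 genes. Among 23 inflammatory genes 7 were higher and 1 lower, with a median of 0. The other lists named here are those whose medians lay outside random lists, which carries no weight in this comparison. Of the lists left out, TGF-beta and matrix genes gave 6 higher and 1 lower of 23. Mesenchymal genes gave 5 higher and 1 lower of 26.

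In total 1908 of 11219 genes differed by at least 2-fold, 545 higher and 1363 lower. With no normalization between arrays 8618 differed, 8460 higher and 158 lower, and median scaling gave 7916 higher and 227 lower. Under all 6 scalings 412 genes stayed higher and 62 stayed lower.

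The exosome array against the MDA-MB-231 array lies within the pair with few detected probes, and this comparison was chosen after the data were seen. Ribosomal RNA was lower on the exosome array. The 28S ribosomal RNA gene RNA28SN5 read 107.8 against 4842 units, 7.99-fold lower, and the 18S gene RNA18SN5 340.8 against 2315 units, 3.39-fold lower. Pyruvate kinase (PKM), the last enzyme of glycolysis, was 4.58-fold lower, the proteasome ATPase PSMC1 4.18-fold lower and FOSB 3.22-fold lower. Higher genes included the RNA-binding protein RBM12, 3.23-fold, the copper chaperone of cytochrome oxidase SCO2, 2.64-fold, and the heat shock cognate HSPA8, at least 4.02-fold.

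Of 1945 genes, 156 differed by at least 2-fold, 85 higher and 71 lower. This balance also rested on the scaling, with 566 higher and 37 lower under median scaling, 637 and 32 with no normalization between arrays, 191 and 113 with the pairs normalized apart, and 476 and 15 from the deposited signals alone. Growth factor and immediate early genes were the only list outside the range of random lists, with a median of -0.48 over 6 genes, of which 1 was lower by 2-fold. Of 15 lists ranked, 0.75 would lie outside by chance, and the median of this list was -0.025 under median scaling and 0 with no normalization between arrays. Median scaling set the median of genes detected on both arrays at 0.82, and 44 genes stayed higher and 15 stayed lower under all 6 scalings.

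Array similarity across 12445 genes followed the pairs as well. Genes are not independent replicates, so these correlations describe the arrays only. The exosome array lay nearest to the MDA-MB-231 array (Pearson's r 0.854, Spearman's rho 0.813, root mean square log2 difference 1.28), and the untreated array nearest to the Dicer antibody array (r 0.776, rho 0.748, root mean square log2 difference 1.35). Across the pairs r lay between 0.0061 and 0.0397, and the root mean square difference between 3.18 and 3.26. These cross-pair r values were 0.167 to 0.207 under median scaling and 0.573 to 0.611 over genes detected on all 4 arrays.

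Whether exosomes moved MCF10A cells toward MDA-MB-231 was asked with a slope across the same genes. The exosome difference had a slope of 0.920 on the MDA-MB-231 difference when both were taken against the untreated array (r 0.915, covariance 8.78), and the Dicer antibody difference a slope of 0.113 (r 0.259, covariance 1.08). The latter slope was 0.288 under median scaling and 0.245 with the pairs normalized apart. Sharing the untreated array alone gave a mean slope of 0.504 and a mean covariance of 0.816 in simulations without any effect. That slope follows from giving every simulated array equal noise, taken from the MDA-MB-231 and exosome arrays. It is therefore no matched baseline for the observed slopes. With no shared array, exosome minus Dicer antibody against MDA-MB-231 minus untreated, the slope was 0.807 (r 0.819), but both of these differences cross the split in detection. Within the pairs, exosome minus MDA-MB-231 against Dicer antibody minus untreated, the slope was 0.013 (r 0.014).

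Both exosome-treated arrays were compared with the untreated array for 11213 genes. The fibroblast markers COL1A2 and LUM were lower on both. At least 2-fold higher on both were 185 genes, and 230 were lower on both. Independent changes would give 166 and 111, but the shared untreated array rules out independence, so these numbers are no yardstick for an absent effect. This split too rested on the scaling, with 53 higher and 2819 lower on both under median scaling, 48 and 2722 with no normalization between arrays, and 45 and 2409 with the pairs normalized apart. The differences correlated across genes with r 0.169 (covariance 0.297). The simulations above, in which only the shared array links the differences, gave 1619 genes changed the same way and a mean r of 0.504, but over 12445 genes and with noise from the MDA-MB-231 and exosome arrays, so they were not matched to these genes. Whether the overlap exceeds that of a shared array alone was therefore not settled. Of 1860 genes at least 2-fold different on the exosome array, 22.3% were at least 2-fold different the same way on the Dicer antibody array. The median difference there was 0.13 for genes higher and -0.66 for genes lower on the exosome array. Because these genes were chosen on the exosome array, part of any smaller value on the other array is regression to the mean.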

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

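The tests weighed here for 3 patterns were chosen only after the results were seen.

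On 2 arrays, those labelled MDA-MB-231 and MCF10A with exosomes, most probes stayed at background, including genes that nearly every cell transcribes. An even loss of signal, from less labelled RNA or a lower scanner gain, is argued against, because the log2 ratio to the untreated array over 486 probes bright on both other arrays had an SD of 4.50 and 4.97, at least 10.7 times the 0.42 found for the Dicer antibody array. Separate chance loss on each array is argued against as well, since 197 of those probes were detected on both dim arrays where independent loss would give 87.3, a ratio of 2.26. Changed expression in intact cells would leave ribosomal protein and oxidative phosphorylation genes detected, yet at most 33.3% of 66 were. Short or broken RNA, as vesicles or degraded samples may hold, stays open, because 2 probes of 1 gene often parted ways, in at least 60.6% of the cases that independent probes would give, and RNA integrity was not analysed here; the extraction notes also cover exosome RNA, while the labels name cells.

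Fibroblast markers were high on the array labelled untreated MCF10A, a breast epithelial line, with COL1A2 at 18125 and LUM at 8848 units. No explanation could be tested on replicates. RNA of fibroblast-like cells under this label stays open. The mesenchymal list, which shares no gene with the fibroblast list, had a median signal at percentile 100 of random lists here. On the Dicer antibody array the percentile was 99.9, so both were near the ceiling and could not part the arrays. The medians themselves were 3460 units here and 429 on the Dicer antibody array. A minor share of fibroblasts among MCF10A cells is argued against by the levels of both lists, as far as epithelial probes respond. The 10 fibroblast markers had a median signal of 6362 units here. The 33 epithelial genes had a median of 54.2 units, at percentile 0.465 of random lists. Of these, 8 were detected, and the highest read 715.8 units. Detection alone could not decide, because 7 of the 15 epithelial genes that another array detected (46.7%) were detected here, neither few nor most. Epithelial probes that do not respond cannot be told apart from absent transcripts for the rest, because 32.0% of the 25 epithelial genes not detected here were detected on another array, neither none nor a majority.

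The Dicer antibody and untreated arrays differed by at least 2-fold in 3865 genes. Exosome RNA added to otherwise unchanged cells is argued against, because 9 of 10 fibroblast markers were lower by at least 2-fold, with a median log2 difference of -4.93, so the added RNA would have to outweigh that of the cells many times over. A difference in the amount hybridised is argued against by the numbers of detected probes, whose ratio was 1.01. RNA of a tumour line under the Dicer antibody label may account for part of it. Such RNA can hold cancer-testis transcripts, which most normal tissues lack. Of these, 5 families were listed before any of their values were seen, though after other families had been seen bright there. On this array 13 of their 34 genes were detected, against 1 on the untreated array. Among the 13, 4 were SSX genes at no more than 78.8 units, near this array's lowest detected signal of 72.1 units. The XAGE family gave 0 of 4 genes. Over all 19948 genes, 11081 were detected on this array and 11107 on the untreated array. An effect of the exosomes themselves stays open and untested, since 1 array per group cannot part it from a difference between the cells.

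Some genes differed in opposite directions on the exosome and Dicer antibody arrays, each against the untreated array. At least 2-fold higher on the exosome array and lower on the Dicer antibody array were 109 genes. The reverse held for 7 genes, among them the translation factors EIF1 and EIF3B, the ribosomal protein gene RPL5 and the early response gene PHLDA1. The difference between the arrays was not tested. With no normalization between arrays 106 of the 109 turned to lower on the exosome array. All 7 kept opposite signs, with log2 differences of 0.71 to 1.03 on the Dicer antibody array, and 1 of them, PHLDA1, kept the 2-fold size both ways. The 7 read 44.4 to 59.5 units on the exosome array, below its lowest detected signal of 81.0. Their lower side is therefore a bound, whose sign could not turn. On the MDA-MB-231 array they read 42.8 to 65.8 units, below its lowest detected signal of 67.9. They thus follow the split in detection and show no separate response to exosomes.

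Probes without a single gene symbol were used in no comparison. Of 17212 such probes, 253 were detected on the exosome array and 871 on the Dicer antibody array without being detected on the untreated array.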

How the results depend on the processing

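Using the log2 of the deposited signals alone, leaving the arrays without normalization between them and normalizing the arrays with many and few detected probes apart were chosen after seeing the data. No paired analysis was possible because each group held 1 array, and there were no replicates to leave out. The authors' value table gave no value for any result that needs the exosome array, since that column holds p-values. Signal over background limits the comparisons that cross the split in detection, where most genes have only a bound on 1 array.

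Across the Dicer antibody and untreated arrays, 1133 of 1208 values of named genes at least 2-fold different kept direction and 2-fold size under the alternatives, 75 kept direction but lost the 2-fold size, and none turned. A detection p below 0.05, no detection filter and only genes detected on both arrays leave measured differences as they are and shrink no bound. Values under these settings could not fail. Named genes were mostly chosen for large differences, so this share does not carry over to all genes. List medians there kept their sign, and in 149 of 154 cases their place outside random lists. The number of genes at least 2-fold different was 3865 in the main values, 1616 without background correction, 2527 in the authors' value table and 1571 with an offset of 50, and the cause was not tested. List medians shrank likewise without background correction and with an offset of 50, the inflammatory one from 2.93 to 1.72 and 1.75 and the cell cycle one from 2.0 to 1.09 and 1.08.

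The counts for MDA-MB-231 against untreated, exosome against untreated and Dicer antibody against exosome were 9065, 8496 and 8143 under median scaling, 9617, 8814 and 8618 without normalization between arrays, 9197, 9165 and 8980 with the pairs apart, and 8486, 7887 and 7617 with the deposited signals alone, where 3 lists lay outside random lists for MDA-MB-231 against untreated. The share of these genes that was higher turned from 69.1%, 69.1% and 28.6% to 0.838%, 2.44% and 97.2%, to 0.499%, 1.87% and 98.2%, to 1.01%, 1.14% and 99.3%, and to 0.389%, 1.76% and 98.3%. The centre of each comparison moved with the scaling. For MDA-MB-231 against untreated, the median log2 difference of genes detected on both arrays was 3.28 in the main values. It was -1.79 under median scaling, -2.14 without normalization between arrays, -1.56 with the pairs apart and -1.76 with the deposited signals alone. Which scaling lies nearest to the RNA levels was not tested. A detection p below 0.05 gave 3685, 3894 and 3814 genes, and turned the similarity of the untreated array with the MDA-MB-231 and exosome arrays to -0.012 and -0.016, whereas median scaling gave 0.175 and 0.167. Only genes detected on both arrays gave 1195, 1188 and 1259 genes, by construction fewer, and 1 list outside random lists for MDA-MB-231 against untreated and 1 for Dicer antibody against exosome. No detection filter gave 11861, 11924 and 11772 genes, of which 44.5%, 45.4% and 53.9% were higher, and 15, 11 and 13 lists. These list counts, 5 each in the main values, carry no weight, since random medians there are mostly 0.

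With only genes detected on both arrays, list medians turned: TGF-beta and matrix to 4.69 and 4.41, from 1 gene each and so no value for the list, ribosomal to 0.45 and 0.24 and oxidative phosphorylation to 0.090 and 0.50 for MDA-MB-231 and exosome against untreated, and ribosomal to -0.094, oxidative phosphorylation to -0.137, stress to -0.746 and hypoxia to -1.349 for Dicer antibody against exosome. This setting drops every gene that fell to background. For exosome against MDA-MB-231 it gave 48.1% higher. RAN turned to -2.28 under median scaling, -2.63 without normalization between arrays, -1.74 with the pairs apart and -1.59 as a mean over probes for MDA-MB-231 against untreated, and to -0.29 with the pairs apart and -1.35 as a mean over probes for exosome against untreated. DNAJA1 turned to -0.86, -1.21 and -0.32 under the first 3 of these for MDA-MB-231 against untreated. With the deposited signals alone, RAN and DNAJA1 turned to -2.59 and -1.20 there. The cause was not tested for single genes.

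The overlap of 415 genes became 2872 under median scaling, 2770 without normalization between arrays, 2454 with the pairs apart, 803 at a detection p below 0.05, 179 with genes detected on both arrays, 2183 with no filter and 2299 with the deposited signals alone. The share changed the same way by exosomes with and without the Dicer antibody, 22.3%, was 33.9% under median scaling, and the cause was not tested. Of 134 values for the planned results under all alternatives, 96 stayed within 1.5 times the main value.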

Other observations

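The tests of cell origin here were written before their results were seen, and the cancer-testis genes were counted after genes of the GAGE, SPANX, PAGE, VCX and MAGEC families were seen to be bright on the Dicer antibody array, so their detection there is no independent finding. Families of these genes share sequence, so a probe may read several members and single gene names within a family are uncertain. On the Dicer antibody array, 39 such genes were detected, among them 11 of 12 GAGE genes with a highest signal of 8309 units, 6 of 10 SPANX genes up to 7045 units, 6 of 12 MAGEA genes up to 805 units and 2 of 3 MAGEC genes up to 2671 units. No GAGE, MAGEA or MAGEC gene was detected on the other 3 arrays. Of these, the MDA-MB-231 and exosome arrays detected only 1584 and 1566 of 19948 genes. Absence there does not show that the cells named by those labels lack these transcripts. The bone protein gene SOST, which restrains Wnt signalling, was at least 30.4-fold higher on the Dicer antibody array than on the untreated array, and matrix Gla protein (MGP), an inhibitor of calcification, was 103-fold higher.

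Whether the dim arrays hold RNA from cells like those on the other 2 arrays was tested with genes at least 8-fold apart between the untreated and Dicer antibody arrays. If the exosome array held RNA of cells like those labelled untreated MCF10A, genes specific to that array should be detected more often, yet 12 of 200 (6%) were detected, against 9 of 114 (7.90%) specific to the Dicer antibody array (Fisher's exact test across genes, two-sided p 0.639). For the MDA-MB-231 array, 11 of 200 (5.50%) and 10 of 114 (8.77%) were detected (p 0.347). Genes are not independent replicates, and so few genes were detected that the origin of the RNA on either array cannot be told apart by this test.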
